A study of Mus musculus with 14 samples.

How the data were processed

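RNA was sequenced from 14 libraries of mouse stem cell lines of 3 kinds. Extraembryonic endoderm stem cells (XEN) gave 3 libraries per arm, and trophoblast stem cells (TSC) and epiblast stem cells (EpiSC) gave 2 per arm. The arms were the METTL3 inhibitor STM2457, at 50 µM for 12 h, and the solvent DMSO; the dose and time are from the sample labels. The labels name a stranded total RNA library kit for every library. Per the submitters' processing notes, reads were checked with FastQC, trimmed with Trim Galore, aligned with STAR to build GRCm39 and counted per gene with featureCounts, with no versions given. The deposited table holds whole-number counts per gene and library, with no normalization applied. Counts from each parental allele were not analysed here. The strand setting of the counting is not given in the sources used here, so values of genes that overlap on opposite strands, such as Xist and Tsix, can hold reads of the other gene.

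Gene names, chromosomes, biotypes and transcript structure were taken by Ensembl identifier from GENCODE mouse release M21, built on GRCm38. This differs from the build of the counting, so no coordinates were used, and 3281 of the 55416 identifiers had no name and joined no gene list.

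All 14 libraries were fitted in 1 model with 6 groups in edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, and a robust quasi-likelihood F test. This left 18430 tested genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each comparison. The comparisons were STM2457 against DMSO in each line, the mean of the 3 line effects, the difference between lines in the STM2457 effect (interaction), and each pair of lines in DMSO. Levels are CPM, counts scaled by the TMM-adjusted library total, given as mean ± SD. Fold changes are log2 ± SE, the SE being the size of the log2 fold change over the square root of F. The log2 CPM used in set tests and per-library measures had a prior count of 2.

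Gene lists numbered 29; 28 had at least 3 tested members and were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Adjusted p-values run over all lists and over the 4 treatment comparisons. The same test with the correlation estimated from the data, member counts adjusted over the list alone, limma's fry and an exact permutation test of each list's mean over the lines stood beside it. The lists held the m6A writer complex, m6A readers and erasers, CCR4-NOT deadenylation, the X-inactivation centre, Xist-dependent silencing factors, X-linked escape genes, Y-linked genes, naive pluripotency, primed pluripotency, trophoblast stem cell, differentiated trophoblast, primitive endoderm, embryonic fibroblast, immediate early, p53 target, interferon response, integrated stress and unfolded protein response, cholesterol synthesis, E2F and DNA replication, mitosis, imprinted, circadian clock, WNT, BMP and TGF-beta feedback, FGF-ERK feedback, Zfp-named zinc finger, ribosomal protein, oxidative phosphorylation, replication-dependent histone and mitochondrially encoded genes.

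X-linked and autosomal protein-coding genes were compared in each library by the difference of their mean log2 CPM and by the X share of counts, with Xist and Tsix left out. Protein-coding genes were also split into quartiles of exon junctions per kb of their longest transcript, of the length of the longest exon, of GGAC motifs per kb (the core of the m6A sequence motif) and of transcript length. These per-library measures were tested by an exact, two-sided permutation of the treatment labels within lines, over all 720 assignments. The smallest p this can give is 0.00278. The permutation ignored the pairing of XEN libraries by number, described below. Permutation within those pairs allows fewer assignments, so its smallest p is larger. It was run only for the X measures in XEN.

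Genes are named by a fixed rule. Mettl3, Xist and Tsix are always given. In each line, the 10 largest rises and the 10 largest falls were taken among called, named genes with a mean of at least 5 CPM in the higher group, where every STM2457 library lay beyond every DMSO library of the line. For the mean effect each line had to move the same way. Up to 4 members of each list with the smallest p, the 5 largest X-linked changes in each direction and the 5 largest differences between lines in each direction were added. Predicted genes, pseudogenes, mitochondrial and small RNA genes were left out of the ranks. For the DMSO comparisons, members of the 3 lineage lists and the fibroblast list are given.

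The groups, comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined. The alternatives were DESeq2 1.42.0, other scalings and filters, a fold minimum of 1.5, fits of single lines, a replicate block, and leaving out each library in turn; those added after seeing the data are named with their values. The numbers were checked for pairing by the correlation across genes of the residuals of STM2457 and DMSO libraries. In XEN it was 0.462 to 0.687 for the same number and −0.553 to 0.00073 for different numbers, so the numbers pair these libraries. For the same number it was −0.132 in TSC and 0.0444 in EpiSC, so the block has no such support there. The methods were tested on simulated data made from the deposited counts of 17974 genes, with 100 changed genes per fold. At a 2-fold change edgeR recovered 67% of them in XEN, 65% in TSC and 66% in EpiSC. At 1.5-fold it recovered 37%, 30% and 24%. False calls numbered 7, 9 and 8. The simulated libraries had the same spread per gene in every line and no pairing. The real XEN libraries were paired and more variable, so these rates need not hold for the real data.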

Results

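The series measured gene expression by RNA sequencing in mouse stem cells of hybrid background after inhibition of METTL3, the enzyme that writes N6-methyladenosine (m6A) on RNA. XEN cells, derived from the primitive endoderm, gave 3 libraries with STM2457 and 3 with DMSO. TSC, derived from the trophectoderm, and EpiSC, derived from the post-implantation epiblast and labelled with the genotype XmolXmus-ΔTsix, gave 2 libraries per arm each. Total counts ranged from 6826496 to 10024628 in XEN, from 17909934 to 20354242 in TSC and from 18640099 to 21097380 in EpiSC. Between 19271 and 21607 genes were detected per library. Throughout, n = 3 libraries per arm in XEN and n = 2 in TSC and EpiSC. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these samples, which is possibly technical. The spread of each gene was estimated over all 3 lines together, though replicates differed more in XEN. A chi-square of counts between 2 replicates, per degree of freedom, was 10.26 to 26.84 in XEN and 2.252 to 5.325 in TSC and EpiSC. The number of calls in 1 line therefore depends on the spread in the others too.

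The first comparison asked which genes set the 3 lines apart in DMSO. Each line carried the regulators of its lineage. The endoderm transcription factor genes Gata4 and Gata6 stood at 616 ± 42.3 and 353 ± 67.6 CPM in XEN, against 22.0 ± 1.4 and 2.79 ± 0.245 in TSC and 0.457 ± 0.154 and 1.08 ± 0.337 in EpiSC. The trophoblast regulators Cdx2 and Elf5 stood at 72.0 ± 3.55 and 168 ± 5.83 CPM in TSC, with 1 and 2 counts over the XEN libraries and 1 count each in EpiSC. The pluripotency gene Pou5f1 stood at 728 ± 19.5 CPM in EpiSC, with 1 count in XEN and 0 in TSC, which allows up to 0.074 CPM, and Nodal, a signal of the epiblast, stood at 125 ± 1.5 CPM in EpiSC and 1.31 ± 0.068 in TSC. Of 23 primitive endoderm genes, 21 were lower in TSC and 22 lower in EpiSC than in XEN. Of 19 trophoblast stem cell genes, 18 were higher in TSC than in XEN and 18 lower in EpiSC than in TSC. Of 22 primed pluripotency genes, 20 were higher in EpiSC than in XEN and 14 higher than in TSC. Of 11 tested embryonic fibroblast genes, 7 were higher in TSC and 9 in EpiSC than in XEN, and 8 higher in EpiSC than in TSC; Col1a1, a fibrillar collagen, stood at 27.1 ± 3.42 CPM in EpiSC and 1.68 ± 0.0971 in TSC. Xist, the noncoding RNA that silences 1 X chromosome, stood at 1450 ± 550 CPM in XEN, 782 ± 84.3 in TSC and 961 ± 53.2 in EpiSC. Tsix, its antisense partner, stood at 3.52 ± 0.879, 0.445 ± 0.081 and 0.487 ± 0.155 CPM, and Mettl3 (ENSMUSG00000022160, chromosome 14) at 50.9 ± 5.87, 32.5 ± 2.67 and 31.1 ± 1.69 CPM. The 7 Y-linked genes held 2 counts in 1 XEN library and 0 counts in the other 13 libraries.

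Between TSC and XEN 13369 genes differed in DMSO (6725 higher and 6644 lower in TSC), between EpiSC and XEN 13221 (6750 and 6471), and between EpiSC and TSC 10018 (5047 and 4971). The XEN libraries also differed from the others in composition. Mitochondrial rRNA took 14.5% ± 1.38 (SD, n = 6) of their counts against 0.0423% in TSC and EpiSC, and replication-dependent histone genes took 0.571% ± 0.0839 against 0.0044%. Differences between XEN and the other lines therefore include differences in library composition. EpiSC also differed from the other lines in genotype, culture medium and tissue of origin, which cannot be told apart. This applies as well to the differences between EpiSC and the other lines given below. With scaling to ribosomal protein genes, an alternative added after seeing the data, the share of higher genes moved from 50.3% to 19.3% for TSC against XEN, from 51.1% to 25.7% for EpiSC against XEN and from 50.4% to 66.7% for EpiSC against TSC.

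In XEN cells, METTL3 inhibition was followed by rises of 8 of 21 tested cholesterol synthesis genes, 5 of 24 interferon response genes and 4 of 8 genes of the m6A writer complex. Dhcr7 and Nsdhl, enzymes of late steps of cholesterol synthesis, rose 3.32-fold (from 21.1 ± 2.5 to 69.4 ± 36.8 CPM; adjusted p = 0.0116) and 2.83-fold (from 15.5 ± 1.66 to 43.5 ± 21.2 CPM; adjusted p = 0.013). Insig1, which holds back the sterol-regulated transcription factor SREBP, rose by 0.71 ± 0.106 from 406 ± 23.1 CPM. Rtp4 and Ifit1, which interferon induces, rose by 1.97 ± 0.402 and 1.56 ± 0.277, the latter from 3.01 ± 0.339 to 8.88 ± 0.197 CPM. Rb1, the retinoblastoma tumour suppressor and brake on entry into DNA replication, fell by 1.07 ± 0.134 on the log2 scale, from 28.9 ± 4.14 to 13.8 ± 0.643 CPM (adjusted p = 0.000298).

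By list, all 21 tested cholesterol synthesis genes had positive fold changes in XEN, with a median of 1.23. Of these, 8 rose and 13 did not pass the test, and 21 passed adjusted over the list alone (camera adjusted p = 1.74e-13; adjusted p = 0.423 with an estimated correlation). Of 24 interferon response genes, 5 rose, among them Oasl2 at 0.97 and Irf9 at 0.44, and 9 did so adjusted over the list alone (median 0.67; camera adjusted p = 1.57e-06; adjusted p = 0.201 with an estimated correlation). Of the 8 genes of the m6A writer complex, 4 rose: Wtap, which anchors METTL3 in nuclear speckles, by 0.72 ± 0.149 from 68.1 ± 16.9 to 112 ± 16.5 CPM, Rbm15b and Rbm15, which guide the complex to RNA, by 0.46 and 0.42, and Cbll1 by 0.48. With 5 of its genes called adjusted over the list alone, the complex had a median of 0.35 (camera adjusted p = 0.000154; adjusted p = 0.0896 with an estimated correlation). Mettl3 itself had a fold change of −0.13 ± 0.115 (adjusted p = 0.636). Of 11 readers and erasers, the cytoplasmic readers Ythdf2 and Ythdf1 rose by 0.73 ± 0.0891 and 0.51, while the list as a whole did not pass (camera adjusted p = 0.189). Mitosis genes were lower as a list, with a median of −0.11 (camera adjusted p = 0.0436; adjusted p = 0.568 with an estimated correlation). edgeR called 0 of the 26 individually, 6 had an unadjusted p under 0.05, DESeq2 called 3, and 2 were lower adjusted over the list alone. Without DMSO library 1 or STM2457 library 2 the mitosis list had an adjusted p of 0.199 and 0.21.

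Of 92 oxidative phosphorylation genes 3 rose in XEN, and the list did not pass (adjusted p = 0.745). These 3 were Ndufaf1 (0.87), Sdhaf2 (0.45) and Ndufaf4 (0.71), which encode assembly factors and not subunits of the respiratory chain. Of 30 E2F and DNA replication genes 3 rose, among them Chaf1b (0.56) and Chaf1a (0.48), subunits of the chromatin assembly factor. Of 371 zinc finger genes 12 rose and 1 fell, of FGF-ERK feedback genes Dusp6, a phosphatase of ERK, rose by 0.95, of 36 imprinted genes Impact and Peg3 fell by 0.76 and 0.68 and Zfp64 rose by 0.45, and of circadian clock genes Arntl, which encodes BMAL1, fell by 0.61. Other large rises were those of Col20a1 (1.78 ± 0.188, from 11.9 to 41.2 CPM), Nxt1 (1.52 ± 0.103; ENSMUSG00000036992), a cofactor of mRNA export, Plekho1 (1.48), Aunip (1.48) and Fkbpl (1.46). Other large falls were those of Mipol1 (−1.28 ± 0.19), Mt1 (−1.15 ± 0.232), a metallothionein that binds metal ions, Dqx1 (−1.08), Capg (−1.04), which caps actin filaments, and Slc31a2 (−0.90). Xist had a fold change of −0.60 ± 0.208 (adjusted p = 0.142; −0.62 and 0.0367 with DESeq2), with 912, 2012 and 1425 CPM in DMSO and 833, 1008 and 1024 CPM with STM2457. Tsix had one of −0.51 ± 0.364 (adjusted p = 0.542). Chic1, of the X-inactivation centre, fell by 0.56.

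In the XEN comparison 764 genes passed the test, 566 higher and 198 lower, and 97 of them changed at least 2-fold. Fitted on the XEN libraries alone 25 passed, 24 higher and 1 lower, and 1499 with the replicate block as well, a setting added after seeing the data. By their residuals, the replicate numbers pair the libraries in XEN. In TSC and EpiSC, with 2 libraries per arm, the residuals neither show pairing nor exclude it. The replicate block covers all 3 lines. With the replicate number as a block 2448 genes passed (1465 higher and 983 lower), 763 of them shared with the fit without it. Xist then fell by 0.54 (adjusted p = 0.0141), and the p53 target list, at an adjusted p of 0.0763 without the block, was lower at 0.000385 (adjusted p = 0.298 with the block and an estimated correlation). The count was 454 without STM2457 library 1 and 414 without DMSO library 3. Of the calls of named genes 68 held in every alternative run for named genes, Dhcr7, Nsdhl and Wtap not among them. Those alternatives were DESeq2, RLE size factors, the replicate block and leaving out each library in turn, and not the fit of XEN alone. Xist had a fold change of −0.85 (adjusted p = 0.00242) without DMSO library 1 and of −0.29 (adjusted p = 0.307) without DMSO library 2. With scaling to ribosomal protein genes 141 genes passed, 88.7% of them higher against 74.1%.

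In TSC, 4 of 8 writer complex genes and 2 of 11 readers and erasers rose, and of 21 cholesterol synthesis genes Insig1 rose. Rbm15 (ENSMUSG00000048109), which brings the writer complex to RNA and to Xist, rose by 0.93 ± 0.112, from 54.3 ± 4.1 to 104 ± 2.1 CPM (adjusted p = 0.00119). Ythdc1, the nuclear m6A reader, rose by 0.91 ± 0.113, from 108 to 203 CPM. Insig1 rose by 1.26 ± 0.135, from 28.9 ± 0.837 to 69.4 ± 1.87 CPM. Fgfbp1, which releases FGFs from the matrix, rose by 1.49 ± 0.197, from 5.77 to 16.3 CPM, and Slc33a1, which carries acetyl-CoA into the endoplasmic reticulum, fell by 1.02 ± 0.148 on the log2 scale, from 26.4 to 13.1 CPM.

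Of the 8 writer complex genes in TSC, 4 rose (Rbm15, Rbm15b 0.56, Virma 0.50 and Wtap 0.79), and 5 did so adjusted over the list alone (median 0.42; camera adjusted p = 2.33e-06; adjusted p = 0.071 with an estimated correlation). Of the 11 readers and erasers, Ythdc1 and Ythdf2 (0.57) rose, and 2 did so adjusted over the list alone (median 0.13; camera adjusted p = 0.0014; adjusted p = 0.169 with an estimated correlation). Mettl3 had a fold change of −0.15 ± 0.135 (adjusted p = 0.699). All 21 cholesterol synthesis genes had positive fold changes, with a median of 0.93. Insig1 alone rose, 20 did not pass the test, and 7 passed adjusted over the list alone (camera adjusted p = 4.22e-13; adjusted p = 0.424 with an estimated correlation). Nsdhl, at 1.31 (adjusted p = 0.0697), and Dhcr7, at 1.30 (adjusted p = 0.112), did not pass. Zinc finger genes were higher as a list, with 5 of 371 rising, among them Zfp229 (1.00) and Zfp62 (0.76), and 8 adjusted over the list alone (median 0.15; camera adjusted p = 9.64e-05; adjusted p = 0.393 with an estimated correlation).

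Lower lists in TSC were those of oxidative phosphorylation (median −0.21; camera adjusted p = 5.13e-09; adjusted p = 0.653 with an estimated correlation), where 1 of 92 genes, the assembly factor Ndufaf1, rose by 0.62, and of mitosis (median −0.14; camera adjusted p = 4.53e-06; adjusted p = 0.201 with an estimated correlation). Of the 26 mitosis genes edgeR called 0, 8 had an unadjusted p under 0.05, DESeq2 called 6, and 3 were lower adjusted over the list alone; Cdc20, the activator of the anaphase-promoting complex, stood at −0.44 (adjusted p = 0.106). Ribosomal protein genes had a median of −0.14 over 86 genes (camera adjusted p = 2.86e-05; adjusted p = 0.785 with an estimated correlation); edgeR called 0 of them, 2 had an unadjusted p under 0.05, and DESeq2 called 0. The p53 target list (median −0.25 over 26 genes; camera adjusted p = 0.00825; adjusted p = 0.764 with an estimated correlation) was lower too, with 0 genes called by edgeR, 7 at an unadjusted p under 0.05, 1 called by DESeq2 and 1 higher adjusted over the list alone. E2F and DNA replication genes had a median of −0.09 over 30 genes, which turned to 0.04 with scaling to ribosomal protein genes (camera adjusted p = 0.0088; adjusted p = 0.544 with an estimated correlation); edgeR called 0, 5 had an unadjusted p under 0.05, DESeq2 called 3, and 1 was lower adjusted over the list alone. The primitive endoderm list was higher (median 0.18, 16 of 23 positive; camera adjusted p = 0.0124; adjusted p = 0.201 with an estimated correlation), with 0 genes called by edgeR, 5 at an unadjusted p under 0.05 and 1 called by DESeq2; without TSC DMSO library 2 its adjusted p was 0.0715. Dab2, an endocytic adaptor, stood at 0.467 CPM in DMSO and 1.27 with STM2457 (adjusted p = 0.111).

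Further large rises in TSC were those of B3gnt8 (1.70 ± 0.327), Rpp25 (1.38), Plcl2 (1.32), Slc27a2 (1.26) and Pop7 (1.20), the last a subunit of RNase P. Further falls were those of Dgka (−0.75), a diacylglycerol kinase, Snx5 (−0.66), Nprl2 (−0.65) and Pex6 (−0.62), which serves peroxisome assembly. Xist had a fold change of −0.19 ± 0.253 (adjusted p = 0.837) and Tsix one of 0.63 ± 0.53 (adjusted p = 0.673). In all, 178 genes passed the test in TSC, 154 higher (86.5%) and 24 lower, 31 of them at least 2-fold. With the replicate block 2036 passed, 1232 higher (60.5%) and 804 lower, and fitted on the TSC libraries alone 4378, 2367 higher (54.1%) and 2011 lower. Without DMSO library 1 or 2 the count was 3 or 4, without STM2457 library 1 or 2 it was 10 or 12, and of 81 calls of named genes 1, that of Insig1, held in every alternative run for named genes. Scaling to ribosomal protein genes gave 82 calls, 98.8% of them higher. That scaling moved the median of all tested genes by 0.111 in TSC and by 0.119 in EpiSC, so the list medians are relative to the other genes.

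The same question was asked in EpiSC. Ltb and Cxcl10, which encode the cytokine lymphotoxin beta and an interferon-induced chemokine, rose by 1.90 ± 0.227 (from 11.5 to 42.8 CPM; adjusted p = 0.00267) and 1.55 ± 0.212 (from 8.88 ± 0.12 CPM; adjusted p = 0.00735). Wnt8a, a WNT ligand, fell by 0.91 ± 0.126 on the log2 scale, from 153 ± 8.78 to 81.2 ± 1.51 CPM, and Lefty1, an inhibitor of Nodal, fell by 0.74 ± 0.154, from 544 ± 13.4 to 326 ± 37.4 CPM. Klf5 and Klf4, transcription factors of naive pluripotency, rose by 0.65 and 0.78. Cdc20 fell by 0.70 ± 0.124, from 294 to 181 CPM (adjusted p = 0.00902).

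Of the 8 writer complex genes in EpiSC, Wtap (0.78, from 77.7 to 134 CPM) and Cbll1 (0.61) rose, and 3 genes did so adjusted over the list alone (median 0.23; camera adjusted p = 0.00291; adjusted p = 0.169 with an estimated correlation). Ythdf2 (0.47) and Ythdc1 (0.47) rose among 11 readers and erasers, whose list had an adjusted p of 0.0993. Mettl3 had a fold change of −0.24 ± 0.136 (adjusted p = 0.439). Immediate early genes were higher as a list, 21 of 24 being positive, with a median of 0.45. Of them, Maff (1.07, from 20.2 to 42.4 CPM) and Zfp36 (0.73), which marks mRNA for decay, rose, and 4 did so adjusted over the list alone (camera adjusted p = 0.000743; adjusted p = 0.48 with an estimated correlation). Interferon response genes had a median of 0.48, and 1 of 24, Cxcl10, rose, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.014; adjusted p = 0.5 with an estimated correlation); without STM2457 library 1 the list had an adjusted p of 0.0578. Zinc finger genes had a median of 0.16, with 11 of 371 higher and 1 lower, or 13 and 1 adjusted over the list alone (camera adjusted p = 2.86e-05; adjusted p = 0.346 with an estimated correlation).

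Oxidative phosphorylation genes were lower in EpiSC, with a median of −0.21 over 92 genes and 2 higher and 3 lower, or 2 and 9 adjusted over the list alone (camera adjusted p = 6.63e-10; adjusted p = 0.603 with an estimated correlation). The falls included Sdhb (−0.73, from 113 to 67.9 CPM) and Ndufv1 (−0.58), subunits of complexes II and I, while the assembly factors Ndufaf1 (0.79) and Sdhaf2 (0.54) rose. In the same libraries mitochondrially encoded genes took 1.40% ± 0.0905 of counts with STM2457 and 1.14% ± 0.0346 with DMSO, and mitochondrial rRNA 0.0499% ± 0.000849 and 0.0377% ± 0.00168, with both STM2457 libraries above both DMSO libraries (exact permutation p = 0.333 for each, the smallest possible for 2 against 2). Ribosomal protein genes had a median of −0.15 (camera adjusted p = 2.71e-06; adjusted p = 0.74 with an estimated correlation); edgeR called 0 of 86, 9 had an unadjusted p under 0.05, and DESeq2 called 5. The mitosis list, with Cdc20 and the kinase gene Plk1 (−0.42) falling and 1 and 4 genes higher and lower adjusted over the list alone, had a median of −0.12, which turned to 0.01 with scaling to ribosomal protein genes (camera adjusted p = 0.00204; adjusted p = 0.4 with an estimated correlation). Cholesterol synthesis genes had a median of 0.27 and did not pass as a list (camera adjusted p = 0.135; 0.00914 with the replicate block, and adjusted p = 0.788 with the block and an estimated correlation); edgeR called 0 of 21, 0 had an unadjusted p under 0.05, and DESeq2 called 0.

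Other rises in EpiSC were those of H2-M2 (1.72), Stx11 (1.31), Il18bp (1.31), which encodes an IL-18 antagonist, Sema7a (1.28), Bhlhe40 (1.21), a transcription factor of the clock list, and on the X chromosome Eras (1.14), a Ras-like gene of embryonic stem cells. Other falls were those of Cnih3 (−2.15 ± 0.379, from 5.60 to 1.26 CPM), Nkx1-2 (−1.49 ± 0.278), Plk5 (−1.21), Pik3r3 (−1.13), Fzd10 (−1.10), a WNT receptor gene, Rec8 (−1.07), a meiotic cohesin gene, and Neat1 (−0.90), the RNA that scaffolds paraspeckles. Pou3f1 rose by 0.50 and Phlda1 by 0.90. Xist had a fold change of 0.04 ± 0.253 (adjusted p = 1) and Tsix one of 0.34 ± 0.526 (adjusted p = 0.84). In all, 309 genes passed the test, 235 higher (76.1%) and 74 lower, 64 of them at least 2-fold. With the replicate block 2427 passed, 1470 higher (60.6%) and 957 lower, and fitted on the EpiSC libraries alone 4321, 2248 higher (52.0%) and 2073 lower. Without DMSO library 1 or 2 the count was 17 or 7, without STM2457 library 1 or 2 it was 17 or 10, and of 93 calls of named genes 5 held in every alternative run for named genes (Mrpl43, Noct, Nxt1, Phax and Tpst2). Scaling to ribosomal protein genes gave 128 calls, 96.9% of them higher.

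Averaged over the 3 lines, 5 of 8 writer complex genes, 3 of 11 readers and erasers, 13 of 21 cholesterol synthesis genes and 4 of 24 interferon response genes rose. Of 26 mitosis genes 9 fell and 1 rose, and of 92 oxidative phosphorylation genes 20 fell and 3 rose. Wtap rose by 0.76 ± 0.0967, Rbm15 by 0.53 ± 0.0623, Rbm15b by 0.40 and Virma by 0.37. Ythdf2 rose by 0.59 ± 0.0574 (adjusted p = 8.31e-06), Ythdc1 by 0.56 and Ythdf1 by 0.37. Mettl3 stood at −0.17 ± 0.0744 (adjusted p = 0.146; 0.0295 with the replicate block). Nsdhl rose by 1.11, Dhcr7 by 1.12 and Insig1 by 0.70. Cdc20 fell by 0.50 ± 0.0682 and Plk1 by 0.26.

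**Figure D1:**
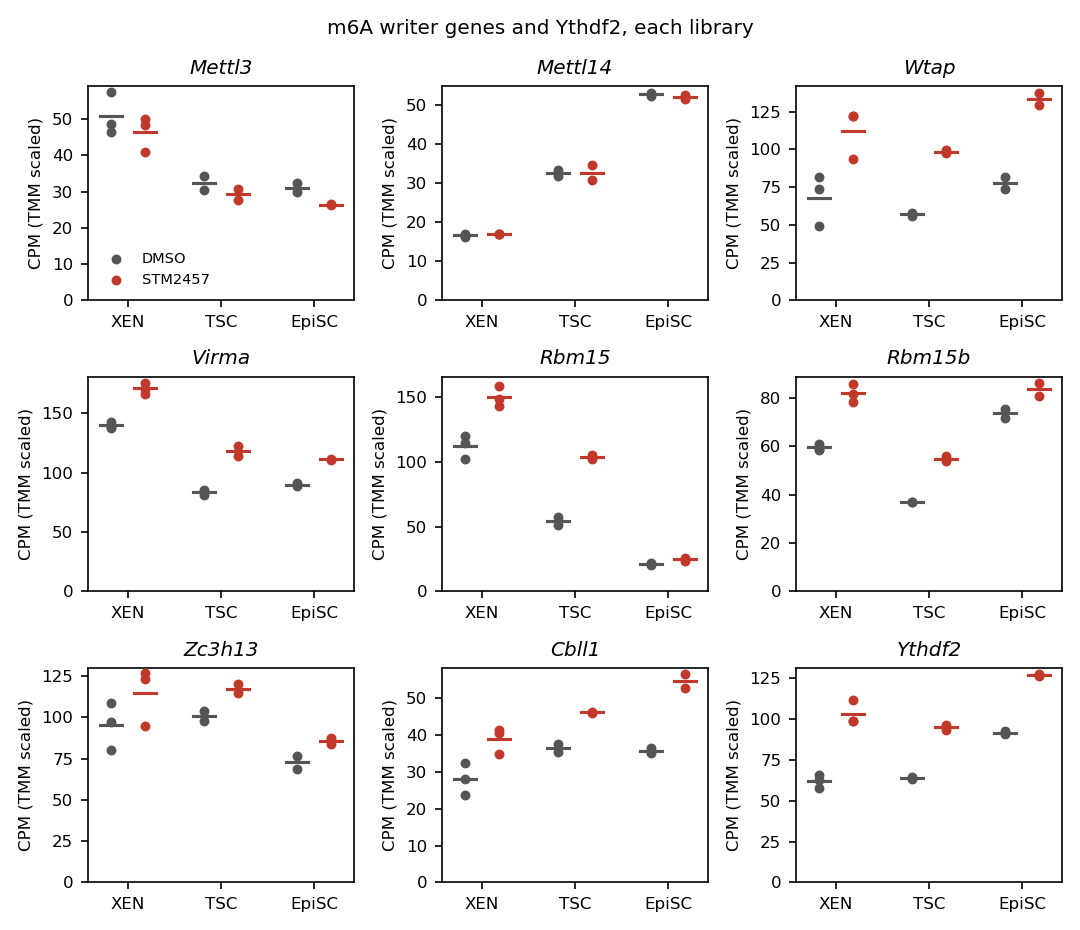
Levels of the 8 m6A writer complex genes and Ythdf2 in each library, in CPM after TMM scaling, by line. Points are libraries and bars are means of DMSO (grey) and STM2457 (red). Wtap goes from 68.1 to 112 CPM in XEN and from 77.7 to 134 CPM in EpiSC, and Rbm15 from 54.3 to 104 CPM in TSC.

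Of 8 writer genes 5 rose in the mean over lines, and 6 were higher and 1 lower adjusted over the list alone (median 0.38; camera adjusted p = 3.39e-05; adjusted p = 0.08 with an estimated correlation). Of 11 readers and erasers 3 rose, and 3 adjusted over the list alone (median 0.11; camera adjusted p = 0.0247; adjusted p = 0.302 with an estimated correlation); the list had an adjusted p of 0.0722 without XEN DMSO library 1 and 0.0555 without TSC DMSO library 2. Of 21 cholesterol synthesis genes 13 rose, or 20 adjusted over the list alone (median 0.76; camera adjusted p = 1.6e-11; adjusted p = 0.459 with an estimated correlation). Of 24 interferon response genes 4 rose, among them Irf9 (0.40), Parp14 (0.70) and Oasl2 (0.69), and 5 were higher and 1 lower adjusted over the list alone (median 0.63; camera adjusted p = 4.6e-05; adjusted p = 0.302 with an estimated correlation). Of 371 zinc finger genes 59 rose and 7 fell, or 67 and 7 adjusted over the list alone (median 0.13; camera adjusted p = 2.35e-05; adjusted p = 0.346 with an estimated correlation).

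Of 26 mitosis genes 1 rose and 9 fell, or 1 and 13 adjusted over the list alone, with a median of −0.14 (camera adjusted p = 5.87e-05; adjusted p = 0.291 with an estimated correlation). Of 92 oxidative phosphorylation genes 3 rose and 20 fell, or 3 and 31 adjusted over the list alone, with a median of −0.15 (camera adjusted p = 2.17e-07; adjusted p = 0.658 with an estimated correlation): the assembly factors Ndufaf1 (0.76) and Sdhaf2 (0.42) rose, and the subunits Sdhb (−0.49) and Ndufv1 (−0.40) fell. Of 86 ribosomal protein genes 4 fell (12 at an unadjusted p under 0.05, 10 with DESeq2), and 0 did so adjusted over the list alone, with a median of −0.09 (camera adjusted p = 0.000593; adjusted p = 0.857 with an estimated correlation). Of 26 p53 targets 1 rose and 4 fell, or 2 and 7 adjusted over the list alone, with a median of −0.19 (camera adjusted p = 0.0191; adjusted p = 0.793 with an estimated correlation): Ccng1 (−0.44) and Bax (−0.27), which promotes cell death, fell and Sesn1 (0.47) rose. That list had an adjusted p of 0.0659 without XEN DMSO library 2 and 0.146 without XEN STM2457 library 3. Of the 30 list calls over the 4 comparisons, 0 hold with an estimated correlation, with or without the replicate block. In the exact permutation test of each list's mean over lines, adjusted over 28 lists, 6 passed: the writers (0.31; adjusted p = 0.0194), readers and erasers (0.14; 0.0259), cholesterol synthesis (0.73; 0.0194), interferon response (0.41; 0.0194), zinc fingers (0.11; 0.0194) and mitosis (−0.14; 0.0259). Oxidative phosphorylation (−0.14; 0.121), ribosomal protein (−0.10; 0.289), p53 target (−0.17; 0.255) and primitive endoderm genes (0.12; 0.0556) did not.

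**Figure D2:**
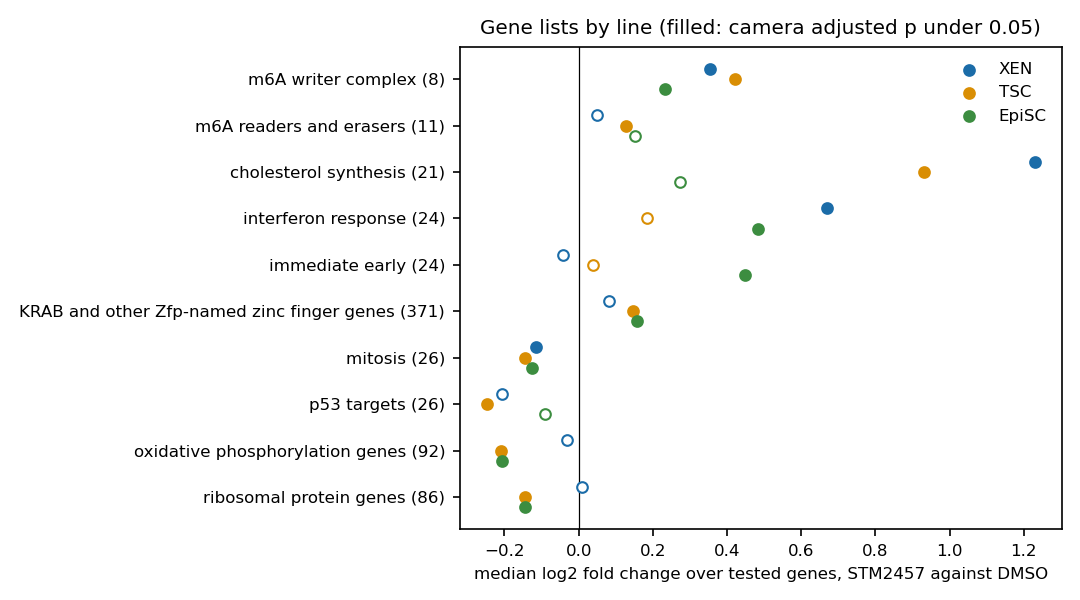
Median log2 fold change (STM2457 against DMSO) of 10 gene lists, with the number of tested genes in brackets, by line. Filled points have a camera adjusted p under 0.05 at the preset correlation. Cholesterol synthesis lies at 1.23 in XEN, 0.93 in TSC and 0.27 in EpiSC. The EpiSC medians of mitosis (−0.12) and p53 targets (−0.09) turn to 0.01 and 0.04, and the XEN medians of readers (0.05) and ribosomal protein genes (0.01) to −0.02 and −0.01, with scaling to ribosomal protein genes; the last does so with RLE size factors too. None of these medians turns relative to the median of all tested genes, which that scaling moved by −0.0441 in XEN and RLE size factors by −0.0169.

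In the mean over lines 2470 genes passed the test, 1434 higher (58.1%) and 1036 lower, 109 of them at least 2-fold; 4722 passed with the replicate block and 2466 were shared. Several of the largest mean changes rest on genes near 0 CPM in at least 1 line. Fzd9, a WNT receptor gene, rose by 2.46 ± 0.495, from 5.13 to 8.76 CPM in TSC and from 2.53 to 5.45 in EpiSC, with 0 CPM in XEN DMSO libraries. Other mean rises included Fgf3 (2.07), Msl3l2 (1.56) and Nrxn2 (1.54), and mean falls Enho (−1.81), Vav3 (−1.28), Tulp1 (−1.11) and Svop (−1.09). The share of higher calls was 69.1% with scaling to total counts and 90.0% of 1380 calls with scaling to ribosomal protein genes. Without TSC DMSO library 1 or 2 the count was 1626 or 1427, without TSC STM2457 library 1 or 2 it was 1462 or 1404, without EpiSC DMSO library 1 or 2 it was 1549 or 1495, and without EpiSC STM2457 library 1 or 2 it was 1505 or 1445.

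The lines shared many of their calls: 54 genes passed in all 3 lines in the same direction, 52 higher and 2 lower (Hnrnpll and Pex6), and 193 in at least 2 lines. Of higher genes XEN and TSC shared 91 against 4.73 for independent lists (Fisher's exact p = 2.93e-98), XEN and EpiSC 123 against 7.22 (p = 1.12e-124), and TSC and EpiSC 65 against 1.96 (p = 4.54e-84). Each line had its own DMSO libraries, but genes with many counts are more easily called in every line, which these expectations leave out. The lines also shared 1 estimate of spread per gene, so a gene of low spread is more easily called in every line too. Among the 52 were Wtap (0.72, 0.79 and 0.78 in XEN, TSC and EpiSC), Ythdf2 (0.73, 0.57 and 0.47), Nxt1 (1.52, 0.92 and 1.13), Phax (1.09, 0.98 and 1.21), the adaptor for nuclear export of small nuclear RNA, Pop7 (1.07, 1.20 and 0.92) and the mitochondrial ribosome genes Mrps2 (1.12, 0.70 and 1.00) and Mrpl43 (1.09, 0.81 and 1.07). These examples beyond Wtap, Ythdf2, Nxt1 and Pop7 were picked after their values were seen. Of the 54 genes, 7 remained at an adjusted p under 0.01. With the replicate block 531 genes were called the same way in every line and 46 in opposite directions. Across genes, fold changes correlated between lines with Spearman's rho of 0.277 (XEN and TSC), 0.275 (XEN and EpiSC) and 0.332 (TSC and EpiSC), and with Pearson's r of 0.0777, 0.1 and 0.126; genes are not independent replicates.

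The interaction tests asked where the response differed between lines, and 3 genes passed. Chst15 (ENSMUSG00000030930, chromosome 7), a sulfotransferase of chondroitin sulfate, rose by 2.60 in TSC, from 0.198 ± 0.0748 to 1.24 ± 0.126 CPM, and had fold changes of 0.27 in XEN and −0.10 in EpiSC. Its TSC effect differed from that in XEN by 2.32 (adjusted p = 0.0329), and the EpiSC effect from that in TSC by −2.69 (adjusted p = 0.00547). Tor1aip2 (ENSMUSG00000050565, chromosome 1), which activates torsin ATPases at the endoplasmic reticulum, rose by 1.14 in XEN, from 425 to 937 CPM, and had a fold change of 0.12 in EpiSC, a difference of −1.02 (adjusted p = 0.0344). D10Wsu102e (ENSMUSG00000020255, chromosome 10) had fold changes of 0.95 in XEN, from 112 to 216 CPM, and −0.22 in EpiSC, a difference of −1.17 (adjusted p = 0.0344). In TSC minus XEN 1 gene passed (911 with an unadjusted p under 0.05), in EpiSC minus XEN 2 (1121) and in EpiSC minus TSC 1 (794). DESeq2, run on all lines with its own size factors and under none of the settings that follow, called 20, 44 and 27. The replicate block gave 56, 179 and 111. For EpiSC minus XEN edgeR called 0 with RLE size factors, with a mean CPM of at least 1 and with protein-coding genes alone (1133, 991 and 937 at an unadjusted p under 0.05). With scaling to ribosomal protein genes, added after seeing the data, edgeR called 0 in each of the 3 differences (807, 1060 and 485 at an unadjusted p under 0.05). Fitted on their own pair of lines, edgeR called 0, 0 and 683 (563, 712 and 2941 at an unadjusted p under 0.05). With 1 library left out the counts ranged from 0 to 1, 0 to 4 and 0 to 1. For the other genes, a call in 1 line and not in another does not show that the lines differ.

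The X chromosome comparison asked whether X-linked RNA changed against autosomal RNA. Over 523 X-linked and 13791 autosomal protein-coding genes, the X minus autosome mean fell by 0.05 on the log2 scale with STM2457, by 0.07 in XEN, 0.06 in TSC and 0.03 in EpiSC (exact permutation p = 0.0111; 0.0111 adjusted over the 2 X measures). The X share of counts fell by 0.139 points, with differences of −0.149, −0.110 and −0.159 points in XEN, TSC and EpiSC. The DMSO means were 2.76%, 3.35% and 5.12%. For the share, every STM2457 library lay below every DMSO library of its line (exact permutation p = 0.00278, the smallest possible; 0.00556 adjusted). Within a line the permutation test cannot reach 0.05; the X minus autosome p was 0.2, 0.333 and 0.333. In the numbered XEN pairs the X minus autosome difference was −0.0671, −0.0872 and −0.0625, lower with STM2457 in 3 of 3 pairs (exact sign-flip permutation p = 0.25, the smallest possible for 3 pairs). Without a block, the X set test did not pass in any line or in the mean (camera p = 0.0812 in XEN, 0.057 in TSC, 0.349 in EpiSC and 0.0604 in the mean; 0.115, 0.0894, 0.37 and 0.093 with an estimated correlation), while with the replicate block p was 0.0709 in XEN, 0.0384 in TSC, 0.293 in EpiSC and 0.0499 in the mean, and with the block and an estimated correlation, a setting added after seeing the data, 0.0311, 0.0202, 0.13 and 0.024. With the block in XEN alone, also added after seeing the data, p in TSC was 0.0452. The set test covered genes of every biotype, 614 X-linked and 17608 autosomal, and so not the same genes as the exact test. Without XEN DMSO library 2 or XEN STM2457 library 3 the set test p in XEN was 0.0328 and 0.0443 and in the mean 0.0367 and 0.0449; without TSC DMSO library 1 it was 0.0403 in TSC.

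Single X-linked genes moved in either direction: 22 rose and 39 fell in the mean over lines, against 1371 and 932 autosomal genes. In XEN 11 rose and 11 fell, and in TSC and in EpiSC 3 were called, each of them higher. With the replicate block 26 rose and 51 fell in XEN, 19 and 30 in TSC, 41 and 26 in EpiSC, and 43 and 85 in the mean. Of X-linked genes 54.7%, 57.0% and 52.6% had negative fold changes in XEN, TSC and EpiSC, against 48.1%, 48.0% and 46.8% of autosomal ones. Rab9, which directs traffic from late endosomes and has a close paralog that can share its reads, rose by 0.92, 0.69 and 0.75 in XEN, TSC and EpiSC, and Utp14a, a gene of ribosome assembly on the list of X-linked escape genes, by 0.43, 0.61 and 0.52. Nsdhl and Ebp (1.21) rose in XEN, where Taf9b (−0.89), a TFIID-related gene, Ap1s2 (−0.66) and Mtmr1 (−0.58) fell. In the mean Tceanc (−0.72) and Apoo (−0.52), a gene of mitochondrial cristae, fell, as did Xlr3a (−0.64), a member of a multi-copy family whose reads cannot be assigned with certainty. Xist had a mean fold change of −0.25 ± 0.138 (adjusted p = 0.288; 0.0142 without XEN DMSO library 1) and Tsix one of 0.15 ± 0.273 (adjusted p = 0.84). Of 8 tested X-inactivation centre genes, Rlim, whose product promotes Xist expression, rose by 0.33 and Chic1 fell by 0.33 in the mean. Of 20 silencing factors 1 rose and 3 fell, among them Ring1 (0.57), Ezh2 (−0.36) and Eed (−0.27), all of Polycomb complexes. These lists and the escape genes did not pass in any comparison (adjusted p from 0.24 to 0.941).

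**Figure D3:**
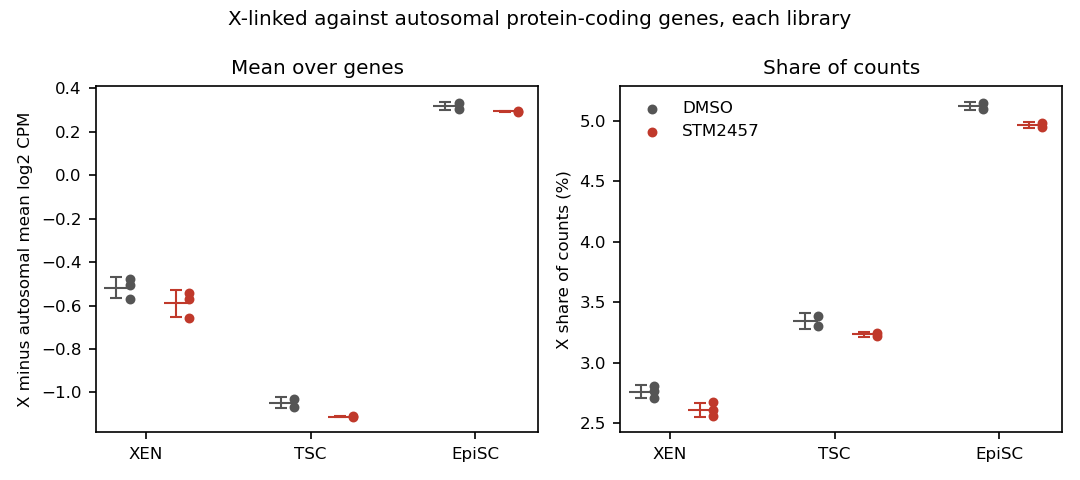
X-linked against autosomal protein-coding genes in each library, as the difference of mean log2 CPM and as the percent of counts on X, by line. Points are libraries, with the mean and SD of DMSO (grey) and STM2457 (red) beside them. The X share lies lower with STM2457 by 0.139 points in the mean over lines.

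Transcript structure was compared because m6A is laid down less where exon junctions are dense. Genes with few junctions per kb of transcript rose against genes with many: the lowest quartile (up to 1.36 per kb) gained 0.21 on the log2 scale over the highest (above 4.44 per kb) with STM2457, by 0.20 in XEN, 0.23 in TSC and 0.21 in EpiSC (exact permutation p = 0.00278, the smallest possible; 0.0111 adjusted over 4 features). In the mean over lines 646 genes of the lowest quartile rose and 76 fell, against 98 and 465 of the highest, 18.0% against 2.74% rising. In XEN 284 rose and 23 fell in the lowest quartile against 29 and 68 in the highest, in TSC 71 and 2 against 11 and 14, and in EpiSC 112 and 8 against 15 and 35. Genes with the shortest longest exon stood at −0.12 against those with the longest (exact p = 0.0194, adjusted 0.0259). By line this was −0.0462 in XEN, −0.182 in TSC and −0.133 in EpiSC. Genes with the fewest GGAC motifs per kb stood at −0.05 against those with the most (exact p = 0.0139, adjusted 0.0259). Short transcripts stood at −0.04 against long ones (exact p = 0.453), where the lines went apart: 0.0555 in XEN, −0.129 in TSC and −0.0451 in EpiSC. Across genes, Spearman's rho of junction density with fold change was −0.203 in XEN, −0.281 in TSC and −0.243 in EpiSC. X-linked genes had a median of 2.42 junctions and 3.23 GGAC motifs per kb, against 2.78 and 4.24 for autosomal genes.

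**Figure D4:**
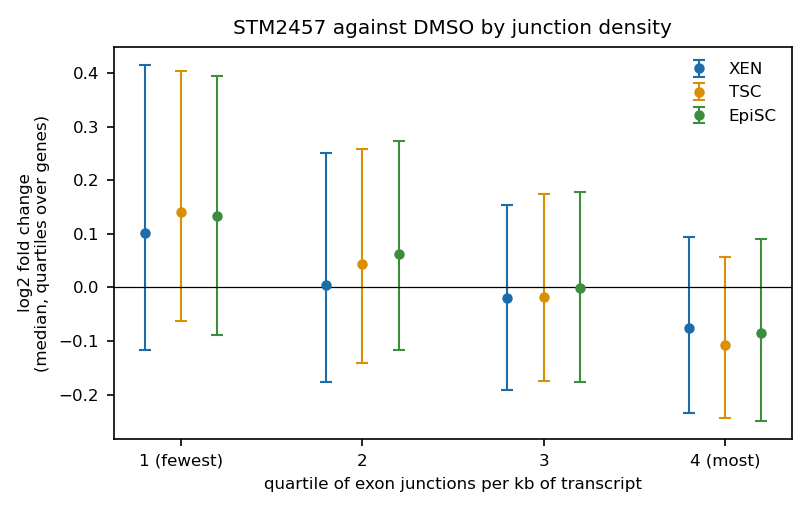
Log2 fold change (STM2457 against DMSO) by quartile of exon junctions per kb of transcript, by line. Points are medians and bars the quartiles over genes. The XEN median lies at 0.10 in the lowest and −0.08 in the highest quartile, the TSC median at 0.14 and −0.11, and the EpiSC median at 0.13 and −0.09.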

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

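The tests of genes with 1 exon, of drift in any chromosome and of the XEN library preparation were chosen only after the result was seen; the others in this part were set before their results were seen. Interaction tests picked out 4 differences between lines. The STM2457 effect on Chst15 was larger in TSC than in XEN by 2.32 (adjusted p = 0.0329), where Chst15 stood at 0.198 CPM in TSC DMSO libraries and 180 CPM in XEN ones. The EpiSC effect on Chst15 differed from the TSC effect by −2.69 (adjusted p = 0.00547). The effect on Tor1aip2 in EpiSC differed from that in XEN by −1.02 (adjusted p = 0.0344). The effect on D10Wsu102e in EpiSC differed from that in XEN by −1.17 (adjusted p = 0.0344).

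Junction-poor transcripts rose against junction-rich ones by 0.21 on the log2 scale. Transcript length, expression level, zinc finger genes alone and genes with 1 exon alone are each argued against as the whole cause: the rise was 0.174 in the longer and 0.250 in the shorter transcripts, at least 0.146 in each of 4 groups by expression, 0.211 without Zfp-named genes and 0.213 without genes with 1 exon (exact permutation p = 0.00278 in each, the smallest possible). Loss of m6A from its own target transcripts is a candidate explanation: within genes of like junction density, those with the most GGAC motifs rose over those with the fewest by 0.0973 (exact permutation p = 0.00278). No other motif was counted beside GGAC, so this rise is not known to be particular to it. Other effects of STM2457 that sort by transcript structure, and RNA quality along transcripts, stay open, and m6A itself was not analysed here.

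X-linked genes fell against autosomal ones by 0.05 on the log2 scale. The fall was −0.0430 against autosomal genes matched on junctions, length and GGAC motifs (exact permutation p = 0.00556). Against autosomal genes matched on expression the fall was −0.0598 (exact permutation p = 0.0139). Each of these argues against the matched property as the whole cause. Without the 50 X-linked genes of most counts the fall was −0.0475 (exact permutation p = 0.0111). Every gene weighs the same in this mean, so leaving out a few abundant genes could change it little. That test cannot tell whether abundant genes carry the fall in the X share of counts, where they weigh more. A drift that any chromosome shows stays open: the largest autosome change was 0.0311 (chromosome 19) in the mean over lines, but 0.0658 (chromosome 19) against −0.0723 for X in XEN, −0.0515 (chromosome 17) against −0.0630 in TSC and 0.0272 (chromosome 13) against −0.0252 in EpiSC. By p-value the X chromosome does not stand out: adjusted over 20 chromosomes it had 0.0555, and chromosomes 14 and 19 had 0.0278. A small effect of METTL3 inhibition on X-linked RNA stays open too, and which X chromosome the shift came from was not analysed here.

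XEN libraries held far more histone, mitochondrial rRNA and small RNA counts than the others. A preparation that kept RNA without poly(A) tails in XEN alone is a candidate explanation: replication-dependent histone genes, whose RNA lacks such a tail, were higher by a median of at least 7.41 on the log2 scale in XEN, while other histone genes had medians of −0.52 and −0.58. With TMM scaling, more cells in DNA replication are argued against, since DNA replication genes had a median of −0.863 in XEN in the comparison where it was lower. The medians of DNA replication and histone genes were not repeated with scaling to ribosomal protein genes. That scaling moved fold changes between lines towards XEN, so the negative signs are known for TMM scaling alone. The labels give the same kit for every library, and line and preparation cannot be separated in this design. Between arms, none of 6 such shares passed an exact permutation test of the mean over lines (p from 0.108 to 0.994), where lines that move apart cancel, as the mitochondrial share did (−0.947 points in XEN, −0.052 in TSC and 0.258 in EpiSC).

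Regrouping the libraries tested whether chance could give as many calls. For the mean over lines, 1 of 100 splits drawn from 360, the real one, called 2470 genes, a share under 0.05. This argues against chance alone for that count. The highest of the others called 1387. That split kept the real arms in TSC and EpiSC and mixed only XEN, so its count holds treatment differences too. Regrouping cannot tell an effect of STM2457 from another difference between the samples of the arms. For lists in the mean, 10 of 100 splits, the real one included, called at least as many as the real one, which called 9. The highest of the others called 11. Each of these splits kept the real arms in TSC, and most of them in EpiSC too, so their list counts hold treatment differences. They do not measure chance alone, so chance is neither shown nor excluded for the number of list calls at the preset correlation. The 10 splits of the XEN libraries are too few for a share under 0.05: the real split called 764 genes and the highest other 514, and 4 lists against 9, with 9 of the 10 splits calling at least as many lists as the real one. The split with 514 genes put DMSO libraries 1 and 3 with STM2457 library 3. It parted only 1 numbered pair and kept the others together. The real split parts every numbered pair, and it called more genes than each of the 3 other splits that do so.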

How the results depend on the processing

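The fits with a block in XEN alone or crossed with one in TSC, the fits without both XEN libraries numbered 2, without XEN, of XEN alone with the block or without mitochondrially encoded genes, the block together with an estimated correlation, and the scaling to ribosomal protein genes were chosen after seeing the data. Where a value below moved, the cause was not tested, except that a fold minimum or a stricter adjusted p counts fewer genes by construction. With arms of 2 libraries, leaving out 1 leaves a lone library that is assumed to vary like the other groups. The depth limits calls of genes near 0 CPM, and at 1.5-fold most simulated changes were missed. For XEN, TSC, EpiSC and the mean, 764, 178, 309 and 2470 calls stood against 1589, 971, 1153 and 3344 with DESeq2. In the simulation, which had no pairing and the same spread in every line, DESeq2 made 23, 23 and 15 false calls in the 3 lines. The replicate block gave 2448, 2036, 2427 and 4722 calls, the block in XEN alone 2909, 2830, 3178 and 5283, and the crossed block 2776, 2591, 2941 and 5127; the block also brought 5 lists past the threshold (p53 targets in XEN, cholesterol synthesis in EpiSC at 0.00914, FGF-ERK feedback in EpiSC and the mean, primitive endoderm in the mean; adjusted p from 0.298 to 0.788 with the block and an estimated correlation), Xist in XEN, Mettl3 in the mean and the X set tests given below, and changed no other call of the lists or of Mettl3, Xist and Tsix. Scaling to ribosomal protein genes gave 141, 82, 128 and 1380. A fold of at least 1.5 left 369 in XEN and 427 in the mean. With no filter on low counts TSC had 332 and EpiSC 585. Fitted alone, XEN had 25 (1499 with the block), TSC 4378 and EpiSC 4321, and TSC and EpiSC fitted without XEN had 4036 and 4455. Without both XEN libraries numbered 2 XEN had 1194 and the mean 4045. With 1 library left out the counts ranged from 414 to 1048 in XEN, 3 to 12 in TSC, 7 to 17 in EpiSC and 1404 to 3247 in the mean.

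The differences TSC minus XEN, EpiSC minus XEN and EpiSC minus TSC had 1, 2 and 1 calls (911, 1121 and 794 at an unadjusted p under 0.05). DESeq2 gave 20, 44 and 27, no filter 9, 66 and 44, the block 56, 179 and 111, the block in XEN alone 175, 401 and 274, and the crossed block 117, 310 and 186. edgeR gave 0, 0 and 0 with scaling to ribosomal protein genes. It gave 0 for EpiSC minus XEN with RLE size factors, with a mean CPM of at least 1 and with protein-coding genes alone. Fitted on their own pair of lines the differences had 0, 0 and 683, and without both XEN libraries numbered 2 the first pair had 2 and 25. With 1 library left out they ranged from 0 to 1, 0 to 4 and 0 to 1. The overlap of 54 genes over lines was 7 at an adjusted p under 0.01, 531 with the block and 280 with DESeq2. Counts between lines in DMSO stayed within 1.5 times under every alternative run. The mean over lines has no fit of single lines.

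The X minus autosome change ranged from −0.0772 to −0.0416 and the X share from −0.154 to −0.125 points, all past the exact test. The junction difference ranged from 0.146, among genes grouped by expression, to 0.250, in the shorter transcripts, all past the exact test too. Junctions are given as lowest minus highest quartile, while the longest exon gave 0.121 and GGAC motifs 0.0526 as highest minus lowest. The share has no value with autosomal scaling, with a median, in the set test or with a block. The X set test p in XEN, TSC and the mean ranged from 0.0328 to 0.269, 0.0403 to 0.188 and 0.0367 to 0.125 with 1 library left out. It was 0.0384 in TSC and 0.0499 in the mean with the block; in XEN, TSC and the mean it was 0.0311, 0.0202 and 0.024 with the block and an estimated correlation, and 0.024, 0.0153 and 0.0175 with the block in XEN alone and an estimated correlation. It was 0.0452 in TSC with the block in XEN alone, 0.0491 in the mean with a mean CPM of at least 1 and 0.0445 in TSC without both XEN libraries numbered 2. Of 30 list calls 0 held with an estimated correlation, with no block or with the block in every line or in XEN alone, 35 lists passed with the block and 28 to 35 with 1 library left out. Calls of named genes were followed only with DESeq2, RLE size factors, the replicate block and each library left out in turn. They were not followed in fits of single lines or with scaling to ribosomal protein genes. Of 373 called pairs of named gene and comparison, 130 kept their call in all of these alternatives, 243 lost it in at least 1, and 0 reversed.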

Other observations

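The fits with a block and an estimated correlation or a block in XEN alone, and the comparison of genes with 1 exon within the lowest junction quartile, were chosen only after the result was seen, and the genes named are those with the smallest p of each list. Lists of cell identity did not pass as lists with STM2457, except primitive endoderm genes in TSC (camera adjusted p = 0.0124; adjusted p = 0.201 with an estimated correlation). Naive pluripotency genes had an adjusted p of 0.896 in XEN, 0.0793 in TSC, 0.322 in EpiSC and 0.22 in the mean, where Klf4 rose by 0.57. Primed pluripotency genes had 0.344, 0.649, 0.744 and 0.637, with Sall4 (0.26) and L1td1 (0.32), of the pluripotency network, rising in the mean. Trophoblast stem cell genes had 0.954, 0.637, 0.344 and 0.892, differentiated trophoblast genes 0.941, 0.954, 0.784 and 0.953, and embryonic fibroblast genes 0.612, 0.196, 0.436 and 0.609. Primitive endoderm genes had 0.475 in XEN, 0.853 in EpiSC and 0.135 in the mean, the last 0.0441 with the replicate block (adjusted p = 0.366 with the block and an estimated correlation); Dab2 (0.64) and Foxa2 (0.41) rose in the mean.

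The next lists did not pass either without the block, though single members of most did in the mean. FGF-ERK feedback genes had 0.637, 0.637, 0.0613 and 0.189, with Dusp6 rising by 0.56 in the mean, and 0.0126 in EpiSC and 0.0394 in the mean with the replicate block (adjusted p = 0.499 and 0.524 with the block and an estimated correlation). WNT, BMP and TGF-beta feedback genes had 0.753, 0.0926, 0.954 and 0.436, with Pmepa1, an inhibitor of TGF-beta signalling, rising by 0.25 in the mean. Circadian clock genes had 0.61, 0.598, 0.647 and 0.896: Bhlhe40 (0.70), Per2 (0.60) and Nfil3 (0.55) rose and Arntl (−0.35) fell in the mean. Imprinted genes had 0.405, 0.637, 0.528 and 0.784, with Impact (−0.41) and Peg3 (−0.28) falling and Zfp64 (0.40) rising in the mean. CCR4-NOT deadenylation genes had 0.135, 0.916, 0.744 and 0.475, with Cnot10 falling by 0.33 in the mean. Integrated stress and unfolded protein response genes had 0.896, 0.941, 0.681 and 0.829, replication-dependent histone genes 0.61, 0.896, 0.362 and 0.954, and mitochondrially encoded genes 0.637, 0.916, 0.196 and 0.842 (in EpiSC 0.0489 with the block in XEN alone, and adjusted p = 0.411 with that block and an estimated correlation). In lines where the text gives no value, immediate early genes had 0.612 in XEN, 0.954 in TSC and 0.344 in the mean, interferon response genes 0.0926 in TSC, zinc finger genes 0.0797 in XEN, p53 targets 0.362 in EpiSC, ribosomal protein genes 0.68 in XEN and E2F and DNA replication genes 0.436 in XEN, 0.953 in EpiSC and 0.649 in the mean.

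A hypothesis was that genes with 1 exon, which have no junction, rise as junction-poor genes do. The 433 such genes rose over genes with several exons by 0.111 on the log2 scale (exact permutation p = 0.00278, the smallest possible), with replication-dependent histone genes left out. In the mean over lines 67 of them rose and 7 fell. All 433 belong to the lowest junction quartile, so their rise is part of the junction pattern and no separate one. Against the 3084 genes with several exons in that quartile they differed by −0.00352 (exact permutation p = 0.886).

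A single identifier without a name (ENSMUSG00002076161) held 1.51% to 2.35% of XEN counts and at most 0.000431% elsewhere.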
